A study of Mus musculus with 6 samples.

How the data were processed

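The series holds 6 samples of mouse total RNA, extracted with Trizol, labelled with Cy3 and hybridised to Illumina whole-genome bead arrays, per the labels. Groups came from the sample titles: adult cardiac fibroblasts with no vector named (called untransduced), fibroblasts 2 and 4 weeks after an empty retroviral vector, fibroblasts 2 and 4 weeks after GHMT retroviruses, and adult heart, with 1 array each. A treatment note about retroviral infection is attached to every sample, heart included, so it does not tell the groups apart. Per the file headers, all 6 arrays carried the name of 1 slide, each with its own position, so slide did not differ between conditions and position cannot be told apart from condition. Scan dates are not given in the sources used here.

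The deposited table holds, per the file headers, an average bead signal per probe and array, an intensity that is neither background-subtracted nor normalized, with the number of beads, the bead standard error of the intensity and a detection p-value per probe. The steps of the array scanner's software behind these deposited values are not given in the sources used here. A second deposited table holds the authors' processed values, an intensity on a linear scale. In it the 6 arrays share the same minimum, maximum and, within rounding, median (110 per array), as arrays do after quantile normalization, with no background subtracted, and each array correlated best with its own column of the first table (r from 0.996 to 1.00 on the log2 scale). The method the authors used for it is not given in the sources used here. Bead numbers ranged from 8 upward, with medians of 43 or 44 per array, so a bead standard error covers spots on 1 array and says nothing about other cultures.

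Main values were computed from the first table with neqc in limma 3.58.1 (R 4.3.3): normexp background correction with the negative-control mean and variance inferred from the detection p-values, an offset of 16, quantile normalization over the 6 arrays and log2. Of 45281 probes, 34885 carried 1 gene symbol in the platform's probe table, 18 carried several and were not named, and 10378 carried none. Symbols of 34807 probes were looked up by gene ID in a RefSeq table of assembly GRCm38.p6. This gave 19057 genes, of which 9172 had more than 1 probe and were represented by the probe with the highest mean value over the 6 arrays. For 45 genes that probe was below background on all arrays while another was above on at least 1. Where a second probe was also above background, 166 of 173 genes changed at 2 weeks and 229 of 235 at 4 weeks had the same sign by it, and 113 and 145 were 2-fold the same way.

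A probe was taken as well above background on an array at a detection p-value under 0.01. With 1 array per condition no test across replicates was possible, so a rule of size was fixed before the data were examined: a log2 difference of at least 1, with the brighter array well above background. Where the dimmer array was not, its value was replaced by the lowest value well above background on that array, or its own value if higher, and the difference is a lower bound. No difference was given where both were below background. The offset added before log2 understates the change of dim genes. Fold values of 2 weeks together are from the mean of both log2 differences.

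Comparisons were GHMT against empty vector at each week and at both, 4 against 2 weeks within each vector, empty vector against untransduced, heart against untransduced, and the GHMT difference over genes higher in heart or in fibroblasts. The shift toward heart is the GHMT minus empty difference as a percent of the heart minus untransduced difference, its median taken over genes at least 4-fold apart. Shares of genes have Wilson 95% intervals. For 32 gene lists with 795 entries, fixed beforehand, members well above background on at least 1 of the 4 vector arrays were used. The medians of 30 lists were placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. The erythroid list, with 0 such members, and the lymphocyte list, with 1, were not placed. Genes named in the text followed a rule fixed beforehand: the 4 factors, the 10 largest measured rises and falls and the 5 largest bounds each way among genes changed at both times, up to 4 members per list changed at both times with up to 2 further members, and the 5 largest each way in the other comparisons. Predicted-gene symbols and unnamed probes were counted and not named.

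The calling steps were tested on simulated arrays made from the real signals, for GHMT against empty vector at both times. Each simulated GHMT array was the empty-vector array of that week with bead error added. The altered genes were well above background on both empty-vector arrays. Of 50 simulated genes per size, 40 at 3-fold, 46 at 4-fold and 48 at 8-fold were called, 0 at 1.5-fold, and 0 of 9059 unchanged genes. The 0 at 1.5-fold follows from the 2-fold rule. Bead error leaves out differences between separate cultures, so the 0 of 9059 is no false-call rate for them. Alternatives covered the background correction, the offset (50), median scaling without quantiles, the authors' values, normalization without heart, the detection threshold (0.05), filters on dim genes, the mean of a gene's probes, 1.5-fold and 3-fold thresholds, a limit of 3 bead standard errors, and limma on the 4 vector arrays with the weeks as replicates. A comparison with untransduced fibroblasts in place of empty vector was added after the data were seen. Other tools were Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.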

Results

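RNA of adult mouse cardiac fibroblasts and of adult mouse heart was measured on 6 single-colour bead arrays, with 1 array for each of 6 conditions. Fibroblasts had been transduced with an empty retroviral vector or with GHMT retroviruses and were collected 2 or 4 weeks later. The labels do not spell out GHMT, which is taken here as the cardiac transcription factors Gata4, Hand2, Mef2c and Tbx5, a combination known from work on turning fibroblasts into heart muscle-like cells. A further fibroblast array, whose label names no vector, is called untransduced here, and the adult heart array completes the set. All samples came from mice 2 months old. Of 45281 probes, between 15007 (heart) and 16075 (GHMT, 4 weeks) were well above background, which left between 8740 and 9158 named genes per array, and each probe value averaged a median of 43 or 44 beads. No condition had a replicate array, so no difference has a replicate check and no p-value is given for the rule of size. A gene was called changed when its normalized signals differed at least 2-fold and the brighter array was well above background. Where the dimmer array was not well above background, the difference is a lower bound, written as "at least".

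The transduced factors were read first, since they bear on the labels. The raw Hand2 signal (probe ILMN_1229467), with background included, was 130 on the empty-vector array and 679 on the GHMT array at 2 weeks, and 121 against 464 at 4 weeks. The background-corrected, normalized values differed by 3.80 and 3.22 log2. Tbx5 (probe ILMN_2664533) was not well above background on either empty-vector array or in untransduced fibroblasts and was measured on both GHMT arrays, a rise of at least 2.72 and 2.02 log2. The second Tbx5 probe was not well above background on any array. The Gata4 probe (ILMN_2817903) was well above background in heart and on no fibroblast array. Of 5 Mef2c probes, the brightest (ILMN_2732465) differed by -0.66 and -0.80 log2 with GHMT and none was 2-fold higher. The probe positions relative to the viral inserts are not given in the sources used here, so the Gata4 and Mef2c values check nothing.

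GHMT against empty vector asks how cultures given the factors differed from control cultures of the same age. Of the lists fixed beforehand, 16 of 21 detected sarcomere genes rose and 18 of 35 detected cell cycle genes fell at both times. Troponin C (Tnnc1), the calcium sensor of cardiac muscle, rose 105-fold in the mean of the 2 weeks, the atrial myosin light chain Myl4 rose 81.8-fold and the Z-disc protein Pdlim3 rose 50.2-fold. Transcripts of the natriuretic hormones Nppa and Nppb, not well above background on the empty-vector arrays, rose at least 84.7-fold and 26.8-fold. At 2 weeks 727 of 9480 genes changed, 394 up and 333 down, and at 4 weeks 928 of 9370 changed, 460 up and 468 down. Together 305 genes rose and 261 fell at both times, against 19.8 and 17.2 for independent lists of these sizes, and 0 genes changed in opposite directions. With only genes above background on every array compared, 190 rose and 232 fell at both times. The comparisons share no array, but the 2 empty-vector arrays were nearly alike, with 0 genes 2-fold apart. The 2 GHMT arrays were close as well, with 36 of 9339 genes 2-fold apart. The labels do not say whether the 2 weeks of a vector came from separate cultures. Part of the overlap can therefore come from likeness of the arrays within each vector, so the numbers for independent lists are no chance level. Across 8192 genes above background on all 4 arrays, the differences at 2 and 4 weeks had a Pearson r of 0.85 and a Spearman rho of 0.742, where genes are not independent replicates. Under limma, with the weeks standing in for replicates and 1 residual degree of freedom, 2723 genes had a Benjamini-Hochberg adjusted p below 0.05. These p-values rest on a spread to which the nearly alike empty-vector arrays contribute, so they do not measure the spread between separate cultures. With the authors' normalized values, which carry no background subtraction, 244 of the 566 genes remained at 2-fold the same way.

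Among genes measured on all 4 arrays, the other large rises were those of Gpc3 (a heparan sulfate proteoglycan, 29.0-fold), Masp1 (a complement protease, 4.05 log2 at 2 weeks and 3.95 at 4 weeks), Ppp1r3c (a glycogen-targeting phosphatase subunit, 3.82 and 3.57 log2), Rrad (a GTPase that restrains calcium channels, 12.2-fold), Cdkn1c (the cyclin-dependent kinase inhibitor p57, 11.5-fold) and Igfbp5 (an insulin-like growth factor binding protein, 10.6-fold). The chymase-family gene Cma2 rose at least 27.2-fold, cardiac actin Actc1 at least 63.3-fold and cardiac alpha-actinin Actn2 at least 21.7-fold. The largest falls measured on all 4 arrays were those of Gpr84 (a fatty acid receptor of myeloid cells, 12.3-fold), Cstdc4 (-3.48 and -3.45 log2), Slpi (a secreted protease inhibitor, 10.3-fold), Csta2 (8.83-fold), the histone genes H2ac15 (7.92-fold) and H2ac12 (7.54-fold), the cell cycle regulator E2f2 (7.58-fold), Lrg1 (6.87-fold), Sema4a (6.79-fold) and Cpxm1 (6.76-fold). Aldolase C (Aldoc) fell at least 5.82-fold, Mcemp1 at least 4.59-fold, Htra3 at least 3.93-fold, Hal at least 3.37-fold and the pocket protein gene Rbl1 at least 2.90-fold. All 15 rises picked by rule (the 10 largest measured and the 5 largest bounds) were also at least 2-fold above untransduced fibroblasts at both times. Of the 15 falls picked in the same way, only those of H2ac15, H2ac12, E2f2 and Rbl1 were also at least 2-fold below untransduced fibroblasts. Other genes rose or fell by more than some of these bounds, so both counts hold for the picked genes only. Cstdc4 and Csta2, and the H2ac genes, belong to families of near-identical genes, so their values are uncertain as to member. The bead standard error of the difference at 2 weeks had a median of 0.118 log2 over the 8469 genes well above background on both arrays. The 2 empty-vector arrays differed from each other with an SD of 0.19 log2 across genes.

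**Figure D1:**
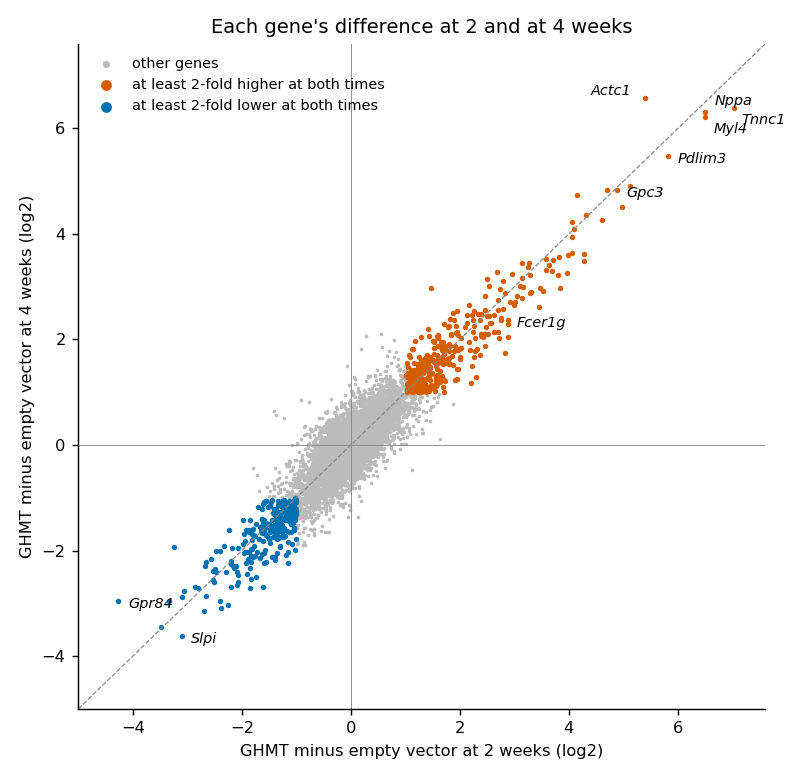
Each point is a gene, with its GHMT minus empty vector difference (log2) at 2 weeks on the x axis and at 4 weeks on the y axis, bounds included. Orange points are the 305 genes at least 2-fold higher at both times, blue points the 261 at least 2-fold lower, grey points all others, and the dashed line marks equal differences.

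Of 21 detected sarcomere genes, 16 rose at both times and 0 fell, led by Tnnc1 (7.03 and 6.39 log2 at 2 and 4 weeks), Myl4 (6.49 and 6.21), Actc1 (at least 5.40 and 6.57) and Actn2 (at least 4.15 and 4.73). The others, listed after their values were seen, were Myh6, Myl2, Myl7, Ttn, Mybpc3, Ldb3, Tcap, Csrp3, Myom1, Myom2, Mybphl and Des. Tropomyosin Tpm1 differed by 0.95 and 1.29 and the chaperone Cryab by 1.17 and 0.80, and neither passed at both times. The list's median was 2.26 and 2.22 log2, or 1.80 and 1.91 with members below background at their bound, above all 10000 random lists matched on expression at both times. All 16 were also at least 2-fold higher than in untransduced fibroblasts at both times.

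Among 22 detected genes of cardiac calcium handling and channels, 9 rose at both times and 0 fell. Sarcolipin (Sln), which regulates the calcium pump, rose at least 4.32 and 4.36 log2, calsequestrin Casq2, the calcium store protein, at least 4.05 and 3.63, and the Popeye-domain genes Popdc2 and Popdc3 rose at least 4.91 and 4.09 at 4 weeks. The calcium channel subunit Cacna2d1 differed by -0.07 and 1.49, and connexin 43 (Gja1) by 0.85 and 0.99. The list's median was 0.86 and 1.06 log2 (0.60 and 0.89 with bounds), at the 100th percentile of random lists at both times. Of 8 detected hormone and hypertrophy genes, 7 rose, among them Nppa (at least 6.50 and 6.30), Nppb (at least 4.97 and 4.52), the Nppa-processing protease Corin (at least 2.83 and 2.88) and Fhl2 (2.49 and 2.45). Rcan1 differed by 0.60 and 0.67. Fhl2 was -1.20 log2 on the empty-vector array at 4 weeks relative to untransduced fibroblasts, and 4 of these 7 genes were also 2-fold higher than in untransduced fibroblasts.

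**Figure D2:**
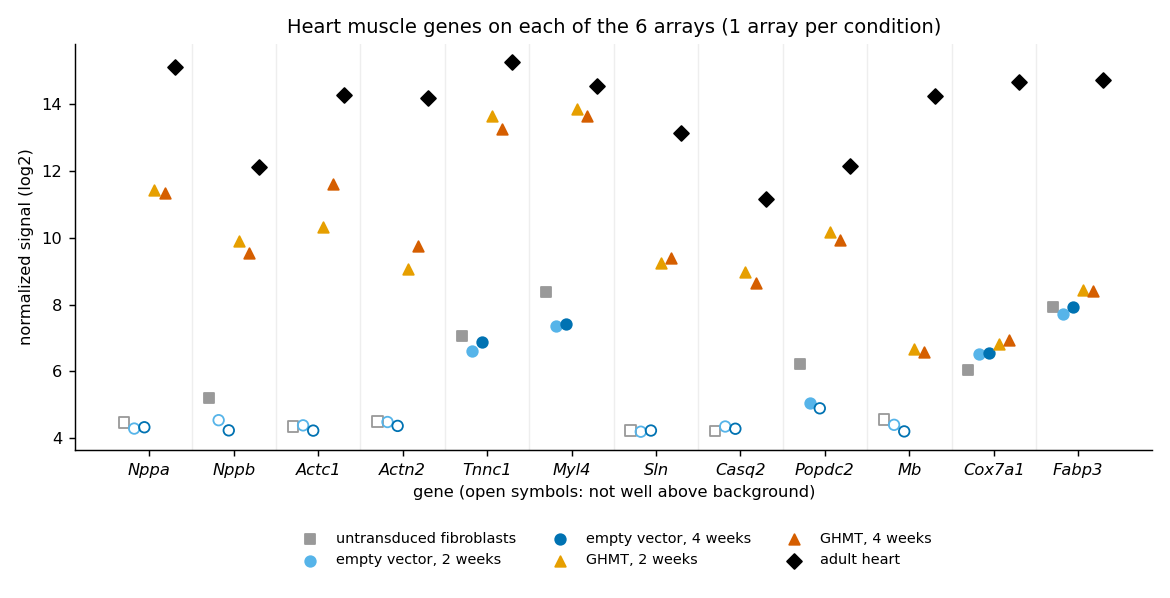
Normalized log2 signal (y axis) of 12 heart muscle and energy metabolism genes (x axis) on each of the 6 arrays, with open symbols where a probe was not well above background. Nppa reached 11.43 and 11.33 with GHMT and 15.10 in heart, while Cox7a1 was within 2-fold of the empty-vector arrays.

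Of 21 other detected cardiac transcription factor genes, 3 rose at both times and 0 fell. Myocardin (Myocd), a coactivator of muscle genes, rose at least 2.21 and 2.46 log2, Tbx20 rose 1.60 and at least 2.07, and Tead1 rose 1.21 and 1.42. Srf (1.12 and 0.85) and Zfpm2 (0.09 and 0.72) did not pass at both times. Only Myocd of these 3 was also 2-fold higher than in untransduced fibroblasts at both times, where Tbx20 differed by 0.50 and 0.69 and Tead1 by 0.10 and 0.30. In the muscle creatine and oxygen list, 5 of 9 detected genes rose, among them Pgam2, a muscle glycolytic enzyme (at least 4.28 and 3.62), Art3 (at least 3.69 and 3.29), myoglobin Mb (at least 1.76 and 1.55) and Cox6a2 (1.69 and 1.56). Ak1 differed by 0.64 and 0.74 and Cox7a1 by 0.30 and 0.41, below 2-fold. Of 8 detected skeletal muscle genes, the light chain Myl1 (at least 4.27 and 3.50) and the acetylcholine receptor subunit Chrnb1 (1.03 and 1.56) rose. Tnni2 differed by -0.19 and -0.63, and Actn3 by at least 0.66 and 0.50, bounds that leave a 2-fold rise open.

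Few mitochondrial energy genes reached 2-fold with GHMT, while most were higher in heart. Of 20 detected fatty acid oxidation genes, Acaa2, the last enzyme of the cycle, rose (2.76 and 2.40 log2) and the fatty acid transporter Slc27a1 fell (-1.08 and -1.23), with list medians of -0.01 and 0.15. All 20 were higher in heart than in untransduced fibroblasts, with a median of 3.57 log2. Pdk4 differed by 0.99 and 1.49 and the fatty acid binding protein Fabp3 by 0.72 and 0.50, against 6.79 in heart. Of 42 detected respiratory chain genes, only the muscle isoform Cox6a2 rose, 40 were higher in heart, and Cox7a2 differed by 0.15 and -0.77 and Ndufb3 by 0.51 and 0.06. In glycolysis, 1 of 14 detected genes changed, Aldoc, which fell, and Pfkp (0.80 and 1.02) and Pdk1 (-0.82 and -0.64) did not pass at both times.

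Of 19 detected smooth muscle genes, 9 rose against empty vector at both times and 0 fell. Desmin (Des) rose at least 3.25 and 3.38 log2, smooth muscle myosin Myh11 at least 3.15 at 4 weeks, myosin light chain kinase Mylk 2.38 and 2.48, and the actin Actg2 2.16 and 2.66, while vinculin (Vcl) differed by 1.25 and 0.88. The list's median was 1.05 and 1.02 log2. The same list was lower on the empty-vector arrays than in untransduced fibroblasts, with medians of -0.74 and -0.65, and against untransduced fibroblasts the GHMT medians were 0.26 and 0.12, with 5 of the 9 genes 2-fold higher. The ligands Tgfb3 (1.97 and 2.08) and Tgfb2 (1.41 and 1.42) rose and Tgfbi, a secreted matrix protein, fell (-2.19 and -1.95) among 15 detected genes of the TGF-beta list. Tgfb1 (-0.64 and -1.09) and Ccn1 (0.86 and 0.97) did not pass at both times. Tgfb3 and Tgfb2 were 0.98 and 0.24 log2 above untransduced fibroblasts at 2 weeks.

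Of 50 detected matrix genes, 6 fell at both times and 1 rose. Mfap4, an elastic fibre protein, fell by 2.40 and 2.95 log2, dermatopontin (Dpt) fell by at least 2.49 and by 2.34, the protease Mmp3 fell by 2.48 and 2.00, and Adamts1 rose (1.53 and 1.84). Of the 50, 13 were lower at 2 weeks and 7 at 4 weeks, and the medians were -0.52 and -0.22. Thbs2 differed by 0.18 and 1.81 and Col1a2 by -1.80 and -0.44. The empty-vector arrays had 11 matrix genes higher than untransduced fibroblasts at both times, Mmp3 among them (2.78 at 4 weeks), and against untransduced fibroblasts the GHMT medians were -0.06 and 0.24, with 2 of the 6 genes still lower. In the fibroblast identity list, 0 of 23 detected genes changed at both times; Itgbl1 differed by 0.90 and 1.32 and Dpep1 by -1.29 and -0.89.

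Of 35 detected cell cycle genes, 18 fell at both times and 0 rose, among them thymidine kinase Tk1 (-2.11 and -2.30 log2), survivin Birc5 (-1.82 and -2.22), the replication helicase subunit Mcm5 (-1.95 and -2.03) and the checkpoint kinase Bub1b (-1.98 and -1.87). Cdc20 (-0.97 and -1.86) and Mcm7 (-0.06 and -1.36) passed only at 4 weeks. The list's median was -1.14 and -1.36, and all 18 were also at least 2-fold lower than in untransduced fibroblasts, where the median was -2.21 and -2.36. The empty-vector arrays were themselves lower than untransduced fibroblasts, with medians of -1.07 and -1.08 and 17 genes lower at both. In the p53 and senescence list of 19 detected genes, Cdkn1c (3.63 and 3.42), the cyclin-dependent kinase inhibitor Cdkn2b (1.09 and 1.66) and Ccng1 (1.12 and 1.08) rose and Lmnb1, a nuclear lamin, fell (-1.29 and -1.63). Sesn1 (-0.95 and -1.39) and Cdkn2a (0.81 and 1.07) did not pass at both times. Of the 3 genes that rose, only Cdkn1c was 2-fold above untransduced fibroblasts.

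Several macrophage and leukocyte markers were lower with GHMT. Of 31 detected markers, the integrin Itgam (at least -1.36 and -1.42 log2), the endotoxin co-receptor Cd14 (-1.67 and -1.56), Coro1a and the chemokine receptor Cx3cr1 (-2.33 and -1.91) fell at both times, and the Fc receptor chain Fcer1g rose (2.87 and 2.37). At 2 weeks 4 were lower and at 4 weeks 14, with medians of -0.35 and -0.78. Marco (-0.85 and -1.90) and Tyrobp (-0.68 and -1.60) passed only at 4 weeks. The empty-vector arrays carried more of these markers than untransduced fibroblasts, 15 of them 2-fold higher at both times with a median of 1.10 at 4 weeks, and against untransduced fibroblasts the GHMT medians were 0.62 and 0.29. Among 25 detected inflammatory genes, the chemokines Cxcl14 (-2.66 and -2.23) and Cxcl12 (-2.56 and -2.16), the acute phase gene Saa3 (-1.16 and -2.24) and the adhesion molecule Icam1 (-1.33 and -1.34) fell and 0 rose. Saa3 was still 4.54 and 3.58 log2 above untransduced fibroblasts, and Cxcl14 and Cxcl12 were lower than there as well. Ccl8 (-0.85 and -1.57) and Tnf (-1.40 and -0.83) did not pass at both times. Of 12 antigen presentation genes, H2-DMb1 fell (-1.06 and -1.36), while H2-Q7 (-0.69 and -1.43) and Ctss (-0.94 and -1.34) passed only at 4 weeks, and the list's medians of -0.33 and -0.72 stood against 0.32 and 0.20 when untransduced fibroblasts were the control. Of 26 interferon response genes, Ifit3 rose at both times (1.73 and 1.87). In this list 6 were higher and 0 lower at 2 weeks, and 1 was higher and 2 lower at 4 weeks. Bst2 (1.31 and 0.30) and Psmb8 (-0.99 and -1.57) passed at a single time.

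Markers of other cell types of the heart moved in both directions. Of 10 detected epicardial and mesothelial genes, Upk3b (3.13 and 3.46 log2), mesothelin Msln (at least 3.15 and 2.78) and Upk1b (2.10 and 2.23) rose and Slpi fell (-3.11 and -3.62). On the empty-vector arrays Upk3b was 3.67 and 3.74 log2 and Upk1b 2.87 and 2.96 log2 below untransduced fibroblasts, and with GHMT both were within 2-fold of them, while Msln was 2-fold above. Bnc1 differed by 0.72 and 0.78, and Cdh1 by at least -0.60 and -0.42, bounds that leave a 2-fold fall open. Of 15 endothelial genes, Flt1, a receptor for vascular endothelial growth factor, rose (1.75 and 1.81) and von Willebrand factor (Vwf) fell (-1.85 and -2.70), with medians of -0.39 and -0.92 (-0.44 at 4 weeks with bounds). Egfl7 (-0.84 and -1.24) and Emcn (-0.38 and -1.05) passed only at 4 weeks. Of 7 pericyte genes, Mcam rose (1.89 and 2.38) and Anpep fell (-1.01 and -1.77), Rgs4 differed by at least 0.79 and by 1.99, and Notch3 by 0.43 and 0.85. Against untransduced fibroblasts none of these 4 calls held at both times, with Flt1 at 0.37 and 0.21, Vwf at -0.62 and -1.64, Mcam at -0.07 and 0.53 and Anpep at 0.17 and -0.59. The endothelial list as a whole was nevertheless lower with this control, with medians of -0.88 and -1.63 (-1.07 at 4 weeks with bounds). Of its 15 genes, 7 were 2-fold lower and 0 higher than in untransduced fibroblasts at both times. No erythroid gene and 1 lymphocyte gene, Cd3e, were detected on the vector arrays, and Cd3e had a bound of 0.19 at 2 weeks and no value at 4 weeks, which leaves its change open.

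The remaining lists held few changed genes. In the unfolded protein and heat shock list of 19 detected genes, the stress factor Ddit3 rose (1.01 and 1.32 log2), and Sdf2l1 (-0.91 and -1.36) and Calr (-0.61 and -0.54) did not pass at both times. No member passed at both times among 14 immediate early genes, where Egr1 differed by 1.63 and 0.11 and Egr2 by 1.53 and 0.89, or among 17 Wnt, BMP and Notch genes, where Sfrp1 differed by -1.49 and -0.87 and Ccn4 by 0.78 and 1.14. The same held for 14 housekeeping genes (Gusb -0.50 and -0.95, Tfrc 0.75 and 0.09), 5 cartilage and bone genes (Sox9 0.90 and 0.11, Bglap2 at least 0.71 and 0.52, which leaves a 2-fold rise open), 4 adipocyte genes (Plin4 0.43 and 1.14, Pparg 0.93 and 0.95) and 4 Schwann and neural genes (Sox10 at least 1.13 at 2 weeks with no value at 4 weeks, Mbp -0.70 and -0.90). Of the 30 lists placed among random lists, 14 had medians outside the central 95% of random lists on the same side at both times. The transduced factors list, with 3 detected genes, is among the 14. Its rise is no separate result, since the treatment supplied these factors. With members below background at their bound, 12 of the 14 lay outside these ranges, and the epicardial list (0.16 and 0.17) and the skeletal muscle list at 2 weeks (0.18) lay inside.

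Because the empty-vector arrays stood apart from untransduced fibroblasts, the counts were repeated after the data were seen with untransduced fibroblasts as the control. Of the 305 genes that rose against empty vector, 194 (63.6%, Wilson 95% interval 58.1 to 68.8%) were also at least 2-fold above untransduced fibroblasts at both times, and 5 were 2-fold below. Among the 305, 60 had been 2-fold lower on both empty-vector arrays than in untransduced fibroblasts. Of the 261 that fell, 91 (34.9%, interval 29.3 to 40.8%) were also 2-fold below, 13 were 2-fold above, and 128 had been 2-fold higher on both empty-vector arrays than in untransduced fibroblasts. Of the 88 genes picked by the naming rule that changed at both times, 36 did not pass the same way with this control, among them Chrnb1, Slc27a1, Ifit3, Icam1, H2-DMb1, Itgam and Cx3cr1. Of the 146 risers that were higher in heart than in untransduced fibroblasts, 120 (82.2%) were 2-fold above untransduced fibroblasts, as were 8 of the 43 (18.6%) that were lower in heart, and these sets were defined with the same untransduced array. In these sets, 15 of the 146 and 30 of the 43 had been 2-fold lower on both empty-vector arrays than in untransduced fibroblasts. Of the 172 genes that fell and were lower in heart, 81 (47.1%) were also 2-fold below untransduced fibroblasts. Of the same 172, 65 had been 2-fold higher on both empty-vector arrays than in untransduced fibroblasts. Both controls use the same GHMT arrays, and 100 simulations of unchanged arrays with the spread of the empty-vector pair gave 0 genes 2-fold apart in both comparisons. That spread leaves out differences between separate cultures, so this 0 is no chance level for them. Independent lists of these sizes among 8908 genes would share 14.0 and 9.72. Part of the excess can come from the shared arrays. With this control 9 lists lay outside the random range at both times, against 14. Of the 14, 7 stayed on their side, the transduced factors and the endothelial list among them. Macrophage markers lay on the opposite side, and fibroblast identity lay below the range at both times only here.

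**Figure D3:**
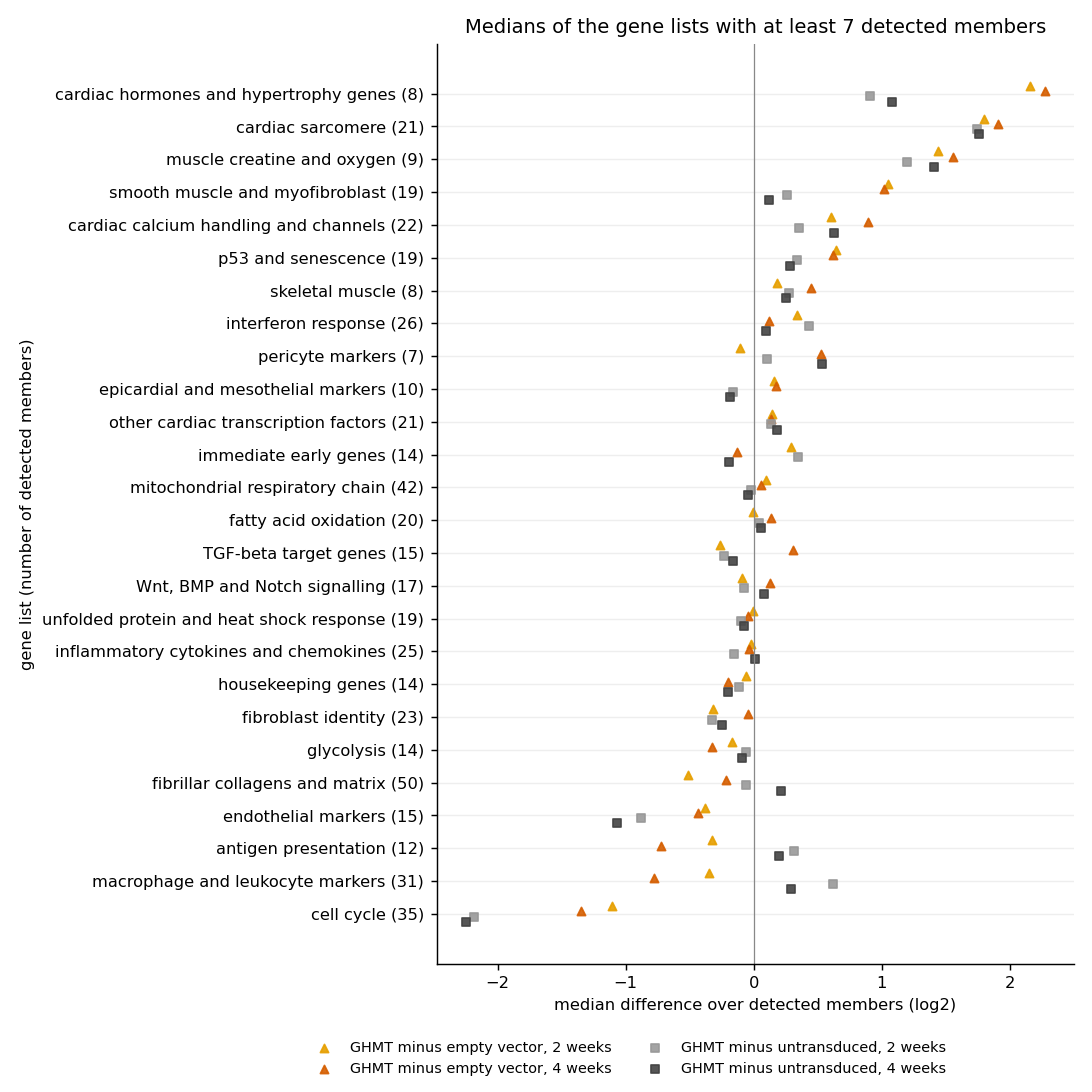
Median log2 difference (x axis, members below background at their bound) over the detected members of each gene list with at least 7 of them (y axis, with the number of members), with triangles for GHMT minus empty vector and squares for GHMT minus untransduced fibroblasts at 2 and 4 weeks. The cardiac lists lie above 0 against both controls, the other cardiac transcription factors by only 0.13 and 0.18 against untransduced fibroblasts. The macrophage, antigen presentation, epicardial and respiratory chain medians changed sign with the control at both times.

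The comparison of 4 with 2 weeks within each vector asks how the cultures differed over time, which 1 array per time does not separate from other differences between cultures. With empty vector, 0 of 9065 genes changed; the largest differences were 0.84 log2 for Svil and -0.89 for Cacna2d1, and the others named by rule were Slc1a6 (0.78), Mcm7 (0.69), Il10rb (0.69), Ndrg1 (0.68), Aqr (-0.86), Tnfrsf11a (-0.82), Ninj1 (-0.79) and Cald1 (-0.77). With GHMT, 36 of 9339 genes changed, 24 higher and 12 lower at 4 weeks. The receptor kinase Epha3 rose by 1.90 log2, the collagen-binding integrin Itga11 by 1.78, the mechanosensitive channel Piezo2 by 1.78, Igfbp3 by 1.74 and Adam23 by 1.63. The immediate early genes Fos (-1.51) and Egr1 (-1.41) fell, as did Il7r (-1.26), Nlrc5 (-1.17) and Rgs1 (-1.12). The spread across genes was 0.19 log2 between the empty-vector arrays and 0.27 log2 between the GHMT arrays. With the authors' normalized values 10 of the 36 GHMT genes still passed.

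Empty vector against untransduced fibroblasts covers vector, culture time and anything else that differed between these cultures. The acute phase gene Saa3 was 52.0-fold higher at 2 weeks and 56.6-fold at 4 weeks, the formyl peptide receptor Fpr2 27.0-fold and 23.6-fold, arginase Arg1 23.4-fold and 24.3-fold, the calcification inhibitor Mgp 21.1-fold and 21.5-fold, and haptoglobin Hp 18.3-fold and 19.6-fold. Prl2c4 (-4.37 and -4.09 log2), Prl2c3 (-4.33 and -4.14), Prl2c2 (-4.31 and -4.14), the macrophage elastase Mmp12 (-3.69 at 4 weeks) and Upk3b fell, though the Prl2c genes are near-identical and cannot be counted as separate. In all, 1032 genes changed at 2 weeks (625 up, 407 down), 1016 at 4 weeks (605 up, 411 down) and 863 at both (534 up, 329 down). The comparisons share the untransduced array, so part of their r of 0.961 across genes comes from it: simulated unchanged arrays gave 0.50, with a covariance of 0.0178 against 0.435 observed and 0 genes 2-fold apart in both. The simulated spread came from the nearly alike empty-vector pair, so this covariance and this count are too low where separate cultures differ. Independent lists would share 41.3 genes up and 18.3 down. With the authors' values 398 of the 863 genes remained. Of 15 endothelial genes, 6 were lower at both times (Emcn -2.76 and -2.69), and the medians of the cardiac hormone list were -0.62 and -0.85 (-0.43 and -0.45 with bounds).

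Heart against untransduced fibroblasts gave the genes called heart-high and fibroblast-high here, the latter meaning only that they were lower in heart than in the fibroblast culture. Among genes measured on both arrays, Cox7a1 was 395-fold, Tnnc1 289-fold, Pgam2 214-fold, Des 206-fold and Perm1, a muscle regulator of mitochondrial genes, 136-fold higher in heart. Genes not well above background in fibroblasts had larger bounds, such as at least 10.10 log2 for Myl2. The glycoprotein Gpnmb (172-fold), the protease inhibitor Timp1 (145-fold), lysyl oxidase Lox (133-fold), neuropeptide Y (Npy, 86.6-fold) and the chemokine Ccl7 (75.5-fold) were lower in heart. Of 9912 genes, 1965 were higher and 2197 lower in heart. Over the 7596 genes well above background on both arrays, the median was -0.12 log2 with quantile normalization and 0.07 with median scaling. Under median scaling 57.6% in place of 47.2% of the changed genes were higher in heart. With the authors' values 2609 of the 4162 changed genes remained.

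The last comparison sets the difference between GHMT and empty vector against the difference between heart and fibroblasts. Genes higher in heart were over-represented among those that rose and genes higher in fibroblasts among those that fell. Of the 1965 heart-high genes, 168 (8.55%, Wilson 95% interval 7.39 to 9.87%) rose at 2 weeks and 187 (9.52%, 8.30 to 10.9%) at 4 weeks, against 2.30% and 2.80% of 5750 genes that did not pass the rule of size between heart and fibroblasts. Of the 2197 fibroblast-high genes, 208 (9.47%) fell at 2 weeks and 291 (13.2%, 11.9 to 14.7%) at 4 weeks, against 2.26% of the other genes at 4 weeks. The fibroblast-high genes included 32 of 35 cell cycle genes, of which 17 fell at both times, 26 of 31 macrophage and leukocyte markers, of which 3 fell, and 15 of 23 fibroblast identity genes, of which 0 fell. Heart-high genes made up 47.9% of the genes that rose at both times, and fibroblast-high genes 65.9% of those that fell. For genes at least 4-fold apart, the median shift from empty vector toward heart was 3.24% and 4.17% of the distance over 930 heart-high genes (bootstrap 95% interval over genes 3.01 to 5.97% at 4 weeks), and 7.57% and 9.53% over 753 fibroblast-high genes (6.76 to 12.3% at 4 weeks). With median scaling the 4-week heart-high shift was 2.27%. With the authors' values 6.17% and 6.25% of heart-high genes rose, and 6.17% and 9.11% of fibroblast-high genes fell. Tnnc1 reached 33.0% and 25.2% of its background-corrected heart signal, Nppa 7.78% and 7.28%, and Mb 0.44% and 0.41%, while the signal of Pdlim3 was 226% and 224% of heart. Across 7283 genes the GHMT difference correlated with the heart difference at r = 0.209 and 0.201. For empty vector at 4 against 2 weeks r was 0.005, which is no reference level, since these 2 arrays were nearly alike. The heart array is whole tissue with several cell types, and intervals on shares cover counting of genes only.

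**Figure D4:**
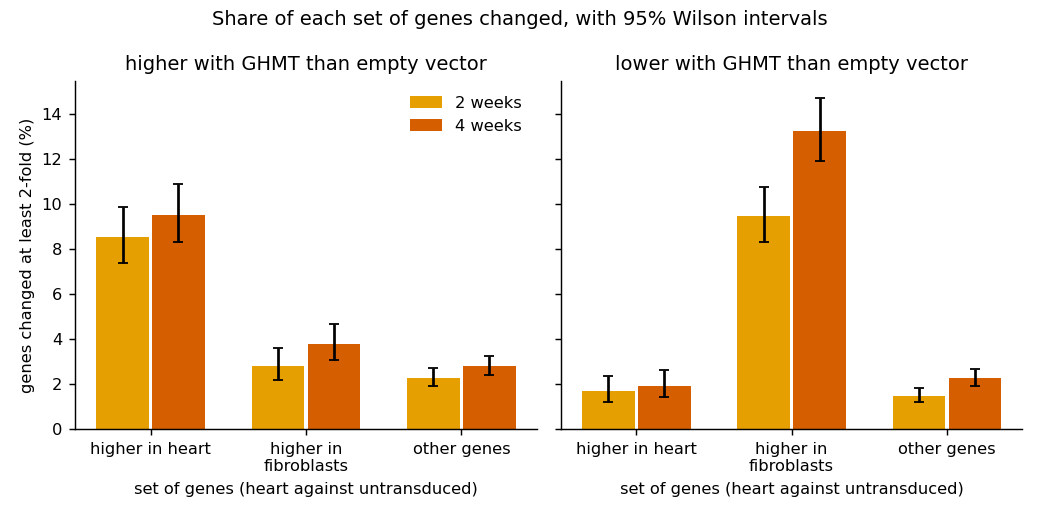
Percent of genes (y axis) that were at least 2-fold higher (left) or lower (right) with GHMT than with empty vector at 2 and 4 weeks, for 1965 genes higher in heart, 2197 genes higher in untransduced fibroblasts and 5750 other genes (x axis). Bars give the share and lines its 95% Wilson interval over genes.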

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

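The values below were selected from the data by fixed rules, and the differences between weeks were not tested, since each week has 1 array per vector. Of 10378 probes with no gene name, 2509 were well above background on a vector array. Of these, 82 were at least 2-fold apart the same way at both times between GHMT and empty vector (54 higher, 28 lower). Among named genes, 566 of 9939 above background on a vector array were so. Between the 2 empty-vector arrays 0 unnamed probes changed, which is no reference level, since these arrays were nearly alike. List medians of GHMT minus empty vector had opposite signs at 2 and 4 weeks for TGF-beta target genes (-0.262 and 0.303 log2), pericyte markers (-0.104 and 0.680), immediate early genes (0.291 and -0.127) and Wnt, BMP and Notch genes (-0.130 and 0.223). Single genes with opposite signs were Itga11 (-1.365 at 2 weeks and 0.560 at 4 weeks), Piezo2 (-1.411 and 0.650), Igfbp3 (-1.236 and 0.512), Fos (1.119 and -0.479) and Il7r (0.137 and -1.365).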

How the results depend on the processing

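The alternatives were fixed before the data were examined, except the use of untransduced fibroblasts as control, which was chosen after seeing the data. Of the counts, shares and shifts that answer a comparison, 112 values stayed within their range and 71 moved. The range of a count was wide. For empty vector against untransduced at both times, 576 genes with the offset of 50 stayed within it, against 863 in the main setting. The limit of 3 bead standard errors left the GHMT counts of 727 and 928 as they were. The 112 is therefore no measure of stability. Of values for named genes, 1430 kept their side of the threshold, 60 lost the call and 7 gained it, and of list medians 385 kept it, 22 lost it, 5 gained it and 8 that lay outside the random range changed sign, all 8 with untransduced fibroblasts as control. Under the alternatives fixed beforehand, no gene was called in the opposite direction except 2 genes in heart against untransduced with the mean of a gene's probes. With untransduced fibroblasts as control, 5 of the 305 genes that rose and 13 of the 261 that fell were 2-fold the other way at both times. Where a signal was not well above background, a difference is a bound or has no value. Without background subtraction or with a larger offset, the background left in dim genes compresses their differences by construction, and a threshold of another size changes counts by construction. For all other settings the cause was not tested.

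With the authors' values, the changed genes numbered 307 at 2 weeks, 397 at 4 weeks and 244 at both for GHMT against empty vector, 452, 460 and 398 for empty vector against untransduced, 10 for GHMT at 4 against 2 weeks and 2609 for heart. Heart-high genes that rose made up 6.17% and 6.25%, fibroblast-high genes that fell 6.17% and 9.11%, and the fibroblast-high shift at 4 weeks was 6.46%. With quantile normalization and no background correction these were 308, 393 and 244, then 445, 456 and 390, then 10 and 2594, with shares of 6.2% and 6.27%, 6.22% and 9.10%, and a shift of 6.65%. With an offset of 50 they were 472, 584 and 371 for GHMT, 664 and 656 for empty vector at 2 and 4 weeks and 15 for GHMT over time, with 7.54% of heart-high genes higher at 4 weeks and 7.46% and 11.01% of fibroblast-high genes lower. All genes counted under these 3 settings were among those of the main setting, and 244 of 566 (43.1%), 244 and 371 (65.5%) of the genes changed at both times remained.

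At 3-fold the counts were 267, 321 and 222 for GHMT, 290, 292 and 248 for empty vector, 6 for GHMT over time and 2416 for heart, with shares of 5.04% and 4.99% of heart-high and 3.19% and 4.82% of fibroblast-high genes. At 1.5-fold they were 1839, 2166 and 1371, then 2635, 2593 and 2130, then 383 for GHMT and 50 for empty vector over time, with shares of 15.6% and 17.2%, and 20.3% and 23.6%. The share of higher among the genes changed in GHMT over time was 66.7% in the main setting, 90% with the authors' values and without background correction, 80% with the offset of 50, 83.3% at 3-fold and 50.1% at 1.5-fold.

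Median scaling gave 7.87% of heart-high genes higher and 14.8% of fibroblast-high genes lower at 4 weeks and a heart-high shift of 2.27%. The mean of a gene's probes gave 8.20% of heart-high genes higher at 4 weeks. With only genes above background on every array compared, 422 genes changed at both times, 6.91% and 7.84% of heart-high genes were higher and 7% and 9.12% of fibroblast-high genes lower. Both a detection p-value under 0.05 and the lack of any filter gave 1 gene for empty vector over time. The limma fit with terms for vector and week, which pairs the vectors within each week, called 2723 genes at an adjusted p under 0.05, from a spread that leaves out differences between separate cultures.

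With untransduced fibroblasts as the control, 9 lists, against 14, lay outside the random range at both times, and 7 of the 14, the transduced factors among them, stayed on their side. The medians outside the random range that changed sign were those of TGF-beta targets at 4 weeks (-0.164), antigen presentation (0.315 and 0.200), epicardial markers (-0.294 and -0.207), matrix at 4 weeks (0.237) and macrophage markers (0.622 and 0.292), and 6 medians inside the range changed sign as well.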

Other observations

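The test of carry-over was chosen only after the results were seen. Of 1965 heart-high genes, 146 rose with GHMT at both times. RNA carried over in the proportions of adult heart, or surviving adult heart muscle cells, would give about the same percent of heart signal for each gene, but the ratio of the 90th to the 10th percentile of that percent over the 146 heart-high genes that rose at both times was 46.4 at 4 weeks (bootstrap 95% interval 24.1 to 81.3) and 52.8 at 2 weeks, and 17 of the 50 brightest heart-high genes were not well above background with GHMT. These values argue against such carry-over as the only source of the rises. A partial contribution stays open, since the 146 genes were picked by their rise. Normalizing together with the heart array is argued against as well, since 100% of the 146 genes kept the call when the fibroblast arrays were normalized alone. A response to the factors is a hypothesis that stays open, as do heart muscle cells whose expression changed in culture and a difference common to both GHMT cultures, which the design does not separate from the factors.

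The empty-vector arrays at 2 and 4 weeks were nearly alike, with 0 genes 2-fold apart. If both arrays had carried the same RNA, different probes of a gene would not move together between them, and the correlation across genes between 2 probes of a gene was 0.0990 (bootstrap 95% interval 0.0597 to 0.138), between the bounds set for either outcome and against 0.461 for the GHMT arrays. The same RNA on both arrays therefore could be neither excluded nor shown by this test. A loss of signal range is argued against, since the raw range on these arrays was 97.4% of that on the GHMT arrays. Cultures that changed little from 2 to 4 weeks may give the same picture, and this was not tested.

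The mast cell proteases Cma2 and Mcpt4, the latter singled out after its values were seen, were at least 4.70 and 4.05 log2 higher with GHMT at 2 weeks, and Fcer1g, also a macrophage gene, was 2.87 log2 higher. Mast cells in these cultures would bring their other abundant transcripts, but 0% of 18 other mast cell genes with a probe were at least 2-fold higher at both times. Only 3 of them, Gata2, Srgn and Hpgds, were well above background on both GHMT arrays, and these were also above background in untransduced fibroblasts, while the raw signal of Cpa3, a major mast cell protease, was 111 and 116 with GHMT and 109 and 106 with empty vector. A change of these genes within the transduced cells is a hypothesis that was not tested.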
